A study of Staphylococcus aureus with 4 samples.

How the data were processed

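Gene expression was measured on 4 two-colour Agilent arrays. Each array set RNA of a Staphylococcus aureus COL culture treated with mupirocin for 10 min against RNA of the untreated part of that culture. Per the labels' protocols, cells grew in a synthetic medium at 37 °C from an optical density of 0.1, and each culture was divided at 0.5. One part received mupirocin at 0.03 µg/ml and the other served as the control. Total RNA was isolated with acid phenol, 10 µg was reverse-transcribed with Cy3- or Cy5-labelled nucleotides, and cDNA carrying 30 pmol of dye was hybridised. Per the series' design text, the 4 hybridisations are biological replicates. The mupirocin sample carried Cy3 in replicates 1 and 3 and Cy5 in replicates 2 and 4. Replicates 1 and 2 shared slide 1, and replicates 3 and 4 shared slide 2, so each slide held both dye orientations. The place of an array on its slide, left or right, went with the dye orientation and cannot be told apart from it.

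The deposited scanner tables were made with Agilent Feature Extraction, per the file headers. They give, for 10807 spots, the mean spot intensity and the median background intensity in both channels, as linear scanner units that the authors deposited without normalization. They also give Feature Extraction's processed intensities, which are background-subtracted and dye-normalized per the file headers, and marks for saturated, dim, non-uniform and outlying spots. The deposited log10 ratio in these tables is processed Cy5 over processed Cy3, since it equalled that quotient within 0.001 for 99.8% of spots on each array. The authors' series matrix holds the same log10 ratio. All its values equalled the log10 ratio of their array within 0.000001 once the sign was turned where mupirocin carried Cy3. Its scale and its direction, mupirocin over control, are therefore known, and it carries no further centring. Its column medians were 0.0104, -0.00268, 0.0179 and -0.0113 for replicates 1 to 4. The statistical test the authors used is not given in the sources used here.

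The analysis started from the unnormalized intensities. Background was corrected with normexp at an offset of 50, and each array was normalized by loess with control spots given no weight, in limma 3.58.1 under R 4.3.3. Log2 ratios were turned to mupirocin over control on every array. Loess sets the bulk of the spots of each array to a log2 ratio near 0, so every value is relative to the average gene on the array and a shift shared by most transcripts would not be seen. Control spots were left out, as were spots that Feature Extraction marked as non-uniform or as population outliers. Saturated spots were kept. Of 10263 spots that were not controls, these marks took 22.0%, 31.8%, 21.5% and 23.1% in replicates 1 to 4. The marks fell on bright spots: in replicate 2 they took 63.7% of the brightest spots and 0.584% of the dimmest, with spots ranked into 10 classes. Around the mean of a probe over the 4 arrays, marked and unmarked values had about the same spread, with SDs of 0.268 and 0.276 in replicate 1 and 0.308 and 0.282 in replicate 2. These spreads were not matched on brightness, so they do not show whether marks go with a larger spread among bright spots. Results with these spots kept are given beside the main ones. That alternative, and the limit to genes measured on all 4 arrays, were chosen after seeing the data. The other alternatives, the tests of genes and lists, the lists themselves and the rule for named genes were fixed before the data were examined.

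The 4020 probes that carry a locus tag of strain COL represent 2465 genes, of which 1208 have 1 probe. Different probes of a gene were averaged on each array over those left unmarked there, so the probes behind a gene can differ between arrays. Among 549 genes with at least 2 probes that could be tested singly, none had probes past the threshold in opposite directions. A gene was tested where it had an unmarked value on at least 3 of the 4 arrays, which left 1711 genes, 1191 on 4 arrays and 520 on 3. Replicate 2 was the missing array for 276 of the 520, so their means weigh the dye orientations unequally. Symbols came from the reference table of S. aureus NCTC 8325, through the NCTC 8325 locus tags that the probe annotation pairs with COL tags. Of 2308 COL tags paired with a single NCTC 8325 tag, 2294 were in that table and 219 carried a symbol or an older symbol. The remaining genes are given by COL tag. The table holds no product names, so lists were matched by symbol only, and the matching by product name that had been planned for ribosomal proteins and aminoacyl-tRNA synthetases was not used. The table is of another strain, so only its names and its gene order were used and no coordinates are printed.

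About 99% of spots were well above background in each channel of each array, and all 4020 probes passed the filter on dim probes, in its main and in its strict form. Non-control spots had median green intensities of 892 to 1195, against 94.9 to 102 for the 79 negative control spots. Between 20 and 64 spots per array and channel were saturated. The number of arrays limits the precision.

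Each gene's mean log2 ratio was tested against 0 with limma's lmFit and eBayes (two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. A further count asked for at least a 2-fold change. A second model added a gene-specific dye effect. The 31 gene lists were tested with camera at a preset inter-gene correlation of 0.01 where at least 3 members were measured. Camera with an estimated correlation, and fry on the genes measured on all arrays, were the alternatives. The rule for named genes took ileS, rsh, relP, relQ and codY whatever their values, the 5 largest rises and the 5 largest falls among genes with a symbol that changed the same way on all 4 arrays, and up to 2 members per list. No probe could be tied to rsh, relP, relQ or codY by symbol, so no value is given for them. Adjusted p-values are limma's, with Benjamini-Hochberg adjustment, unless camera or fry is named, and SDs are over arrays.

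On simulated data for the comparison of mupirocin with control, with the spread and missing values of the 1711 genes, the test recovered 32.8% of genes changed by 0.5 on the log2 scale, 79.1% of those changed by 1 and 97.0% of those changed by 2. Of its 145 calls, 4.14% were false. In another run the measured dye effects took the place of part of the random spread, which was reduced to make room for them. These shares were then 28.4%, 88.1% and 100%, and 1.37% of 146 calls were false. With less random spread, that run does not show what dye effects on top of the full spread would do. Each run changed 67, 67 and 66 genes by these amounts and drew genes independently. In the data 910 of 1711 genes passed and neighbouring genes correlated, so these rates need not hold for the data. Alternatives covered the background correction, the normalization, the filter on dim probes, a dye term, the slide as a random block, each slide alone, the brightest probe per gene, an intensity trend in eBayes, the authors' series matrix values, and each replicate left out. A gene then needed values on at least 2 of the remaining arrays. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.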

Results

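The series asked how the transcriptome of S. aureus COL responds to mupirocin, an antibiotic that blocks isoleucyl-tRNA synthetase, the enzyme that charges tRNA with isoleucine. COL is a methicillin-resistant laboratory strain. The data are 4 two-colour arrays, each a biological replicate in which cells exposed to 0.03 µg/ml mupirocin for 10 min were compared with the untreated part of their own culture. Mupirocin carried Cy3 on 2 arrays and Cy5 on the other 2. Of 2465 genes with a COL tag on the array, 1711 could be tested once spots marked as outliers were left out. All 2465 could be tested with those spots kept, and values of that kind are named as such.

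After 10 min of mupirocin, ileS (SACOL1206), which encodes the drug's target, was among the most increased transcripts. Outlier marks had removed too many spots of ileS for the main test, which left replicates 1 and 3 with log2 ratios of 3.09 and 2.66. With the marked spots kept, the ileS log2 ratio was 2.89 ± 0.26 (SD, n = 4, limma adjusted p = 7.39e-06), a 7.40-fold rise seen on all 4 arrays. Of 23 measured ribosomal protein genes, 19 fell (adjusted p = 0.178 for the list with an estimated correlation), with rpsF (SACOL0437) at -1.93 ± 0.38 (SD, n = 4, limma adjusted p = 8.12e-05). The leucine biosynthesis gene leuD (SACOL2049) and the chaperonin gene groEL (SACOL2016) rose.

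Across the genome, 910 of 1711 tested genes (53.2%) changed, 449 higher and 461 lower with mupirocin. At least 2-fold changes were found for 331 genes, 169 higher and 162 lower. Of the 910, 897 had the same sign on every array that measured them, as did 262 of the genes not called. The calls were made on these same arrays, so this agreement in sign is largely built in. In the main test, the largest changes belonged to genes that the reference leaves without a symbol and that were chosen after their values were seen. SACOL1033 rose by 5.18 ± 0.68 on the log2 scale (SD, n = 4, limma adjusted p = 1.45e-05), a 36.2-fold rise, with 4 of its 8 mupirocin readings saturated. SACOL0742 rose by 3.38 ± 1.05 (SD, n = 4, limma adjusted p = 0.000129). SACOL0430 stood at -3.80 ± 0.48 (SD, n = 3, limma adjusted p = 3.89e-05) with 5 of its 8 control readings saturated, and its neighbour SACOL0429 stood at -3.49 ± 0.88 (SD, n = 3, limma adjusted p = 0.000126) with 6 of 12 saturated. Saturation makes such ratios understate the change. Neither SACOL0430 nor SACOL0429 had an unmarked value in replicate 2. Their values with marked spots kept were -3.32 ± 1.04 (SD, n = 4, limma adjusted p = 6.76e-05) and -3.04 ± 1.30 (SD, n = 4, limma adjusted p = 0.000243). With marked spots kept, the lowest measured log2 ratio was that of SACOL0964, at -4.58 ± 0.57 (SD, n = 4, limma adjusted p = 6.30e-06), a gene the main test did not include. In that setting, 1449 of 2465 genes changed, 686 higher and 763 lower, 507 of them at least 2-fold, and 899 of the 910 main calls were made again in the same direction. Within slide 1 alone 530 genes changed, and within slide 2 alone 487. With the slide as a random block 1293 changed, at a negative consensus correlation of -0.731 within slides, each of which held opposite dye orientations. A negative correlation narrows the standard errors of the means, so 1293 may overstate the number of changed genes.

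**Figure D1:**
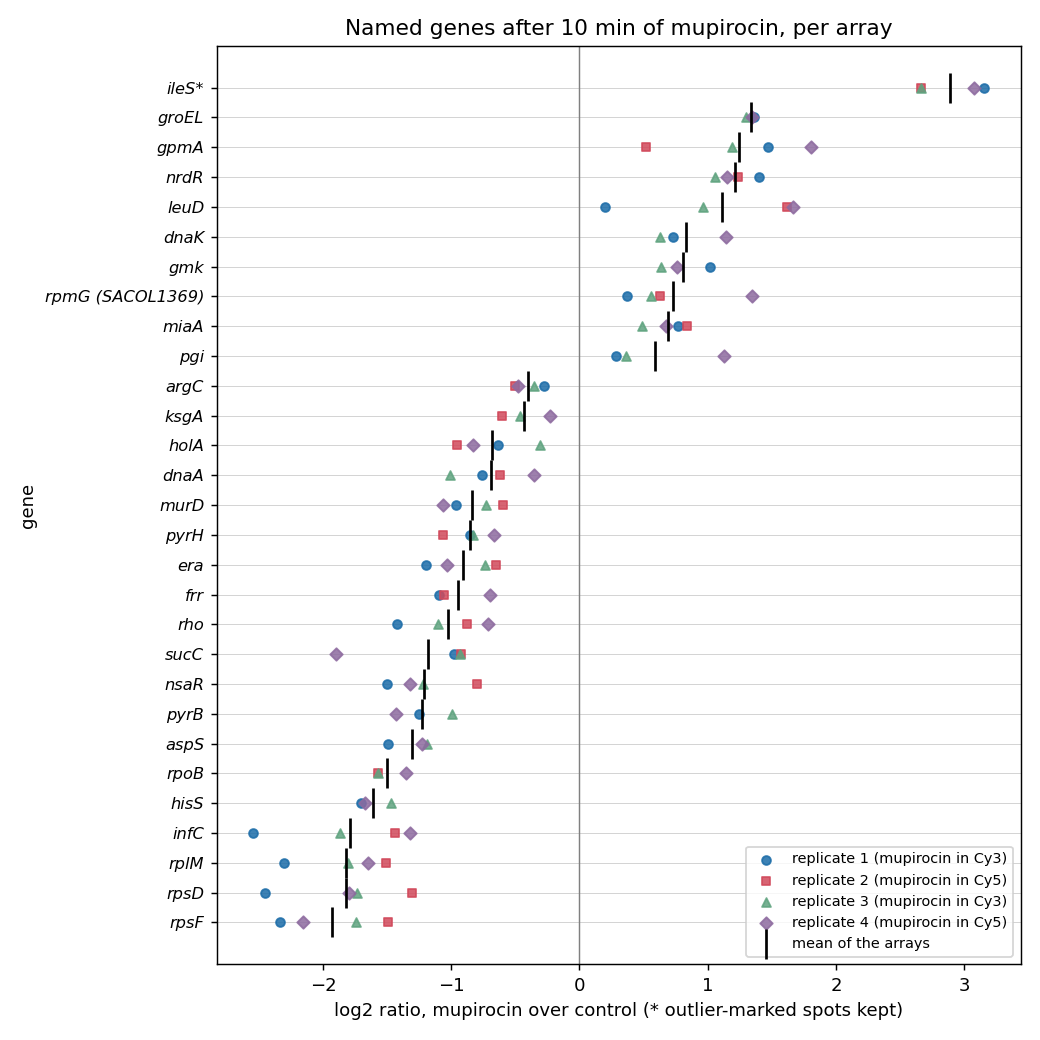
Log2 ratios of mupirocin over control (x axis) of the named genes (y axis), with 1 marker per array and a bar at the mean of the arrays shown. The asterisk marks ileS, plotted with outlier-marked spots kept. The 4 ileS values lie between 2.66 and 3.16, and the values of rpsF, rpsD, rplM and infC all lie below -1.

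The ribosomal protein list was the only one of 9 tested lists that camera called. Of 23 members measured in the main test, 19 fell, 1 rose and 3 did not pass, with a median log2 ratio of -1.02 (camera adjusted p = 1.15e-06, or adjusted p = 0.178 with an estimated correlation). Adjusted over the list alone, the counts were again 19 lower and 1 higher. Besides rpsF, the large decreases included rpsD (SACOL1769) at -1.82 ± 0.47 (SD, n = 4, limma adjusted p = 0.000129) and rplM (SACOL2207) at -1.82 ± 0.34 (SD, n = 4, limma adjusted p = 8.12e-05). The exception was rpmG (SACOL1369), 1 of 2 genes of that name, which rose by 0.73 ± 0.43 (SD, n = 4, limma adjusted p = 0.00652). The other, SACOL1608, was at -0.87 ± 0.24 (SD, n = 4, limma adjusted p = 0.000734). Among all 42 matched members, measured with marked spots kept, 35 fell, 1 rose and 6 did not pass, and the median was -1.07 (adjusted p = 0.164 with an estimated correlation). Camera then tested 16 lists and again called no other, the next smallest adjusted p being 0.0970. Adjusted over the list alone, the counts of the lists below equalled those over all genes tested, except that 1 DNA replication gene, nrdF (0.45), passed in addition.

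Of 5 translation factor genes measured, 2 fell and 3 did not pass (camera adjusted p = 0.181, or 0.587 with an estimated correlation). Those that fell were frr (SACOL1278), for the ribosome recycling factor, at -0.95 ± 0.22 (SD, n = 3, limma adjusted p = 0.00147), and infC (SACOL1727), for initiation factor IF-3. The infC spot was saturated in the control channel on all 4 arrays, so on the mean of the arrays its transcript was at least 3.47-fold lower with mupirocin, taking the saturated spots at their value (log2 ratio -1.79 ± 0.55, SD, n = 4, limma adjusted p = 0.000202). Both measured genes of ribosome assembly fell, too few for camera, the GTPase gene era (SACOL1624) at -0.91 ± 0.25 (SD, n = 4, limma adjusted p = 0.000674) and the rRNA methyltransferase gene ksgA (SACOL0536) at -0.43 ± 0.19 (SD, n = 3, limma adjusted p = 0.0402). The ksgA call was lost without replicate 1 (-0.43) or replicate 2 (-0.34), with slide 2 alone (-0.34) and with an intensity trend in eBayes (-0.43). Once marked spots were kept, 6 of 9 translation factor genes and 6 of 8 ribosome assembly genes fell and the rest did not pass.

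Of 5 aminoacyl-tRNA synthetase genes in the main test, 4 fell and 1 rose (camera adjusted p = 0.113). The neighbours hisS (SACOL1686) and aspS (SACOL1685) fell most, at -1.61 ± 0.12 (SD, n = 3, limma adjusted p = 0.000134) and -1.30 ± 0.17 (SD, n = 3, limma adjusted p = 0.000319). The genes lysS at -0.60 and pheS at -0.66 fell too, and argS rose by 0.41. Keeping marked spots brought 13 synthetase genes into the test, of which 9 fell, ileS and argS rose, and cysS (0.22) and alaS (-0.10) did not pass. Of the genes for charging the other branched-chain amino acids, leuS stood at -1.37 ± 0.58 (SD, n = 4, limma adjusted p = 0.000475), and valS at -0.36 ± 0.25 (SD, n = 4, limma adjusted p = 0.0453), both with marked spots kept and chosen after their values were seen.

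**Figure D2:**
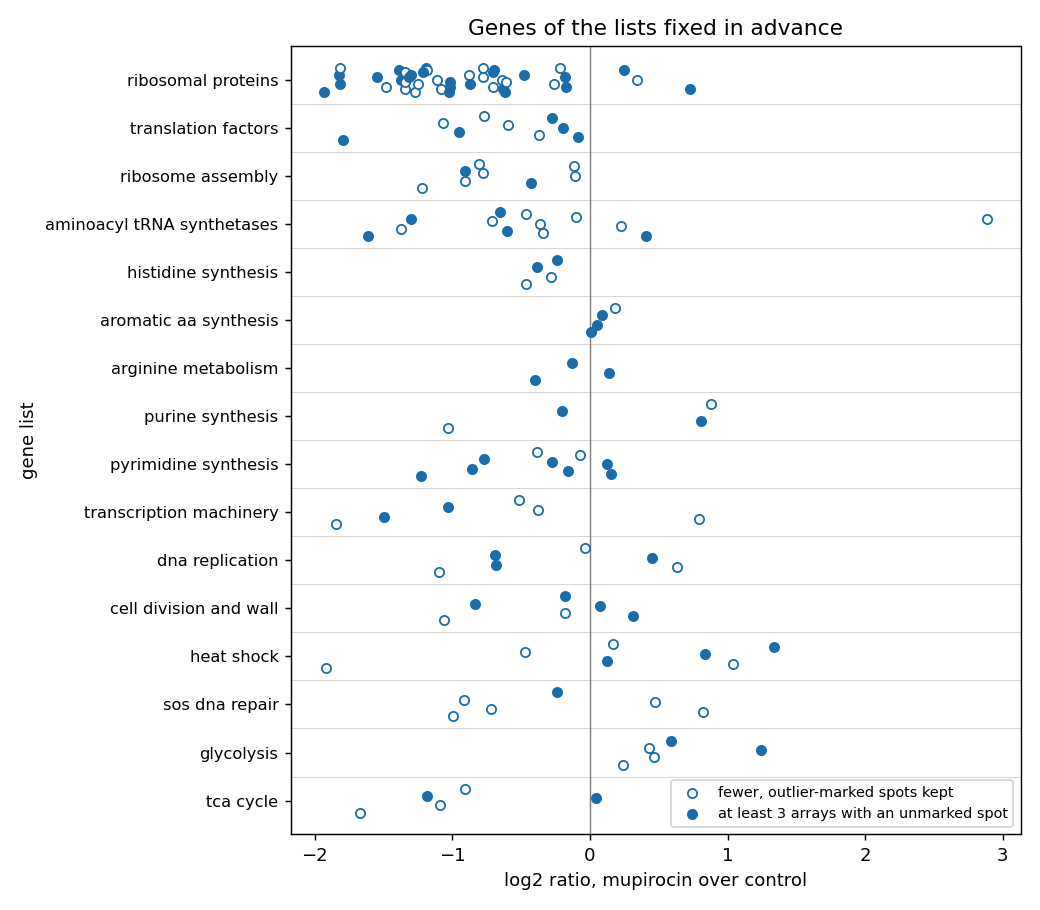
Log2 ratios of mupirocin over control (x axis) of each measured gene of the 16 lists with at least 3 genes on the array (y axis; vertical scatter within a list has no meaning). Filled points have unmarked spots on at least 3 arrays, and open points are the other genes with outlier-marked spots kept. Most ribosomal protein genes lie below 0, and ileS stands apart from the other synthetase genes at 2.89.

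Both members of the transcription machinery list in the main test fell, too few for camera, the RNA polymerase beta subunit gene rpoB (SACOL0588) at -1.50 ± 0.12 (SD, n = 3, limma adjusted p = 0.000163) and the termination factor gene rho (SACOL2113) at -1.03 ± 0.31 (SD, n = 4, limma adjusted p = 0.000526). When marked spots were kept, 5 of 6 members fell and rpoZ rose by 0.79. The rpoB value was then -1.03 ± 0.18 (SD, n = 4, limma adjusted p = 0.000163).

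In amino acid biosynthesis, leuD rose by 1.11 ± 0.69 (SD, n = 4, limma adjusted p = 0.00394), with its mupirocin spot saturated on 3 of the 4 arrays. It was the only branched-chain biosynthesis gene with a symbol in the reference. It lay in an unbroken stretch of 9 genes, SACOL2042 to SACOL2050, all of which rose with marked spots kept, with a median of 1.67 and a range of 0.97 to 2.19. Their mean was 0.73 and 1.22 on the arrays with mupirocin in Cy3 and 1.89 and 2.11 on those with mupirocin in Cy5. Mupirocin spots were saturated in 40 of 64 readings, in 8 of the 9 genes, which makes these ratios understate the rise. Of these, 5 were tested in the main setting and all 5 passed. None of 3 measured genes of aromatic amino acid synthesis passed (camera adjusted p = 0.910), nor did either of 2 genes of histidine synthesis. In arginine metabolism, 1 of 3 genes fell, argC (SACOL0169) at -0.40 ± 0.11 (SD, n = 4, limma adjusted p = 0.0173, camera adjusted p for the list = 0.802). That call was lost when any replicate was left out, with values of -0.44 to -0.37. Keeping marked spots, 1 of 4 histidine genes fell, and of 2 genes for glutamate and serine metabolism 1 rose.

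**Figure D3:**
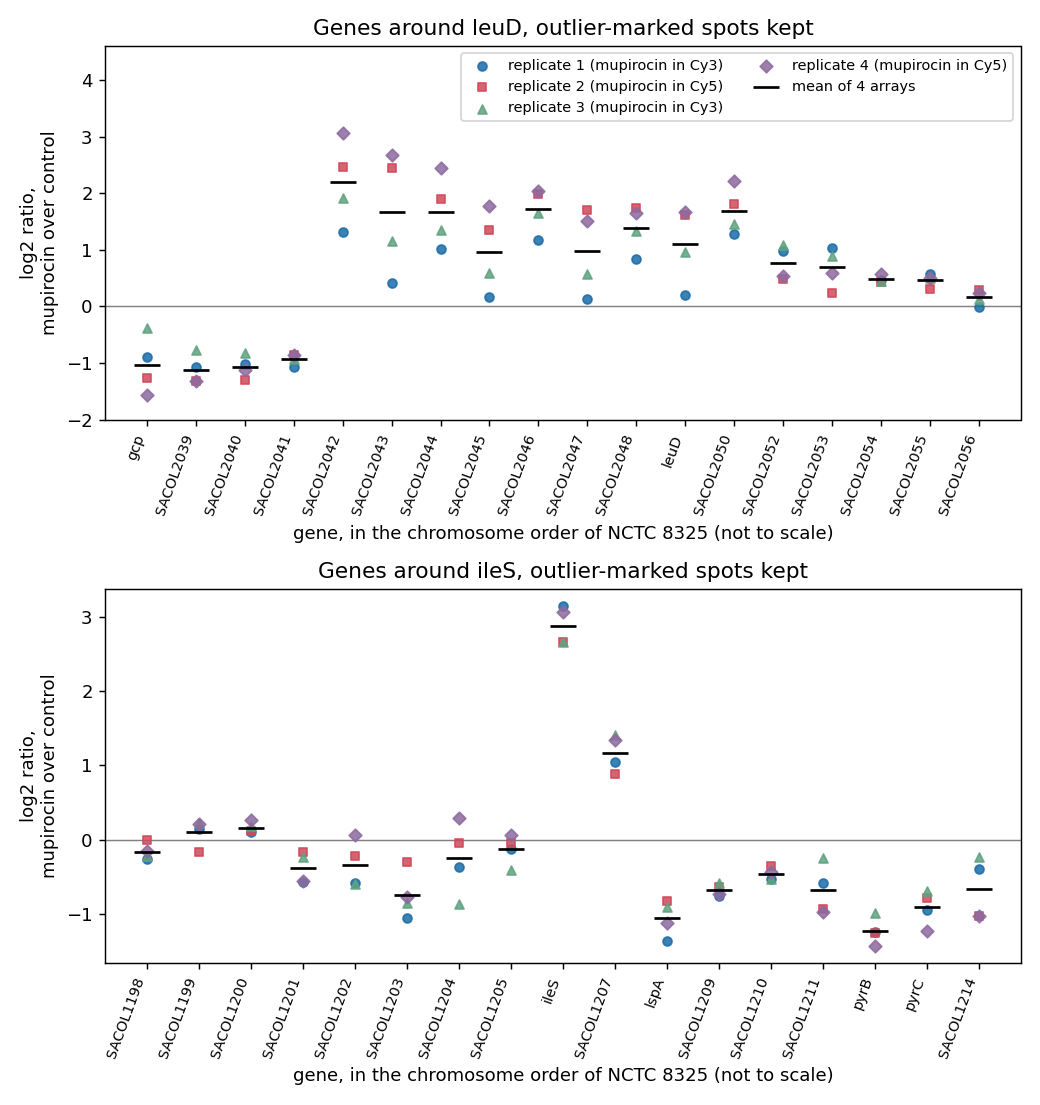
Log2 ratios of mupirocin over control (y axis) of the genes around leuD and ileS, in the gene order of NCTC 8325 (x axis, not to scale), with 1 marker per array, a bar at the mean of 4 arrays and outlier-marked spots kept. The 9 genes from SACOL2042 to SACOL2050 lie above 0 on every array, and ileS at 2.89 stands between SACOL1205 at -0.13 and SACOL1207 at 1.17.

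In nucleotide metabolism, 3 of 7 measured pyrimidine genes fell and 4 did not pass (camera adjusted p = 0.199). These were pyrB (SACOL1212), for aspartate carbamoyltransferase, at -1.22 ± 0.22 (SD, n = 3, limma adjusted p = 0.000469), pyrH (SACOL1277), for UMP kinase, at -0.85 ± 0.16 (SD, n = 4, limma adjusted p = 0.000559), and pyrC at -0.77. Of 2 purine genes, gmk (SACOL1221), for guanylate kinase, rose by 0.81 ± 0.19 (SD, n = 3, limma adjusted p = 0.00286) and adk (-0.20) did not pass. In the test that kept marked spots, purH fell to -1.03 and guaA rose by 0.88. The transcriptional repressor gene nrdR (SACOL1733) rose by 1.21 ± 0.14 (SD, n = 4, limma adjusted p = 0.000129). In DNA replication, 2 of 3 genes fell (camera adjusted p = 0.597), the initiator gene dnaA (SACOL0001) at -0.69 ± 0.27 (SD, n = 4, limma adjusted p = 0.00309) and holA (SACOL1643), for a DNA polymerase III subunit, at -0.68 ± 0.28 (SD, n = 4, limma adjusted p = 0.00342). With marked spots kept, 3 of 6 fell, recF (-1.10) in addition, while nrdI (0.63) and nrdF (0.53) rose.

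Among stress genes, 2 of 3 measured heat shock genes rose (camera adjusted p = 0.181), the chaperone genes groEL, by 1.33 ± 0.03 (SD, n = 3, limma adjusted p = 0.000234), and dnaK (SACOL1637), by 0.83 ± 0.27 (SD, n = 3, limma adjusted p = 0.00332), whereas clpP (0.13) did not pass. Once marked spots were kept, 3 of 7 rose and 2 fell, among them hslU at -1.92. The groEL value was then 1.17 ± 0.26 (SD, n = 4, limma adjusted p = 0.000138), with replicate 2, absent from its main value, at 0.80. The single DNA repair gene in the main test, mutL (-0.24), did not pass. With marked spots kept, 2 of 6 repair genes rose, including recA by 0.82, and 4 fell.

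In central metabolism, both measured glycolysis genes rose, the phosphoglycerate mutase gene gpmA (SACOL2415) by 1.24 ± 0.55 (SD, n = 4, limma adjusted p = 0.000989) and the glucose-6-phosphate isomerase gene pgi (SACOL0966) by 0.59 ± 0.47 (SD, n = 3, limma adjusted p = 0.0354). The pgi call was lost without replicate 1 (0.75) or replicate 3 (0.71), and without replicate 4 (1.13 by itself) the mean of the 2 remaining arrays, of 1 dye orientation and not tested, was 0.32. Of 2 genes of the citric acid cycle, sucC (SACOL1262), for a subunit of succinyl-CoA synthetase, fell to -1.18 ± 0.48 (SD, n = 4, limma adjusted p = 0.000787) and fumC (0.04) did not pass. With marked spots kept, 4 of 5 glycolysis genes rose and 4 of 5 citric acid cycle genes fell. In cell wall synthesis, murD (SACOL1196) was the 1 of 4 measured genes that fell, at -0.84 ± 0.21 (SD, n = 4, limma adjusted p = 0.000773, camera adjusted p for the list = 0.741). Among 6 measured with marked spots kept, murD and mraY (-1.06) fell and murB (0.40) and murG (0.47) rose. The single measured gene of lipid synthesis, acpP (-0.12), did not pass. The oxidative stress gene tpx (0.17) did not pass and atpC of ATP synthase rose by 0.71, both with marked spots kept. Outside the lists, the response regulator gene nsaR (SACOL2646) fell to -1.21 ± 0.30 (SD, n = 4, limma adjusted p = 0.000249), and miaA (SACOL1323), for a tRNA-modifying enzyme, rose by 0.69 ± 0.15 (SD, n = 4, limma adjusted p = 0.0015). For 10 lists, among them stringent response, virulence regulators and sigma B regulon, no gene could be matched by symbol.

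The dye was tested as a source of differences in the same genes. In the model with both effects, no gene passed for dye after limma's adjustment, while 1084 genes passed for mupirocin. For dye, 388 of 1711 genes had an unadjusted p under 0.05 in limma, more than chance alone would give. Dye effects on single genes are therefore not excluded. The median absolute effect was 0.145 for dye and 0.44 for mupirocin, on the log2 scale. Across 2465 genes with marked spots kept, arrays of the same dye orientation correlated at 0.951 and 0.924. Arrays of opposite orientation, turned to mupirocin over control, correlated at 0.802 to 0.860. With marked spots left out, the values were 0.948 and 0.909 for the same orientation and 0.786 to 0.852 for the opposite. Genes are not independent replicates, and no p-value is attached to these correlations.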

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

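The dye model and the sign-turning test were chosen before the results were seen. The bounds by which the dye model is weighed here and the test on correlations between dye orientations were chosen after. With 28 sets of 4 array values examined, 3 held an array far from the others, and chance alone flags about 1 set in 20. For sucC the log2 ratio was -1.90 in replicate 4 and -0.98 to -0.93 in the other replicates (gap over range 0.948), and without replicate 4 it was -0.95. The share of spots with an outlier mark was 31.8% in replicate 2 and 21.5% to 23.1% elsewhere (gap over range 0.844). The median log2 ratio over 2465 genes, marked spots kept, was -0.07 in replicate 2 and between -0.01 and 0.00225 elsewhere (gap over range 0.836).

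A signal also appeared outside the genes of the comparison. The array carries 6233 probes with no COL tag, 2425 with tags of other strains or plasmids and 3808 with no locus tag. Of 4957 that were tested, 1430 passed the threshold, 585 higher and 845 lower with mupirocin, 373 of them by at least 2-fold. Their median green intensity was 576, against 98.8 for negative control spots and 2324 for COL-tagged probes. What these probes detect in COL was not tested.

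In all, 910 of 1711 tested genes changed. Dye bias as the main cause is argued against by the model with both effects, in which 0 genes passed for dye and 1084 for mupirocin. The correlations between arrays of opposite dye orientation argue against it too. The lowest was 0.802 with marked spots kept and 0.786 with them left out. Arrays of like orientation correlated more closely, at 0.951 and 0.924 with marked spots kept and 0.948 and 0.909 with them left out. In this, dye and place on the slide cannot be told apart. Sampling chance alone is argued against by the same correlations, since separate cultures of opposite dye orientation correlated at 0.786 or more with marked spots left out. The sign-turning test cannot decide this by itself. Turning the signs of arrays gives 8 splits, of which 1, the real one, reached 910 genes, and the highest of the other splits gave 0, but 8 splits are too few for a share under 0.05. The treated and untreated parts of each culture differed by design in mupirocin, and limma's test of each gene's mean tested that difference. How mupirocin led to the changes was not tested.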

How the results depend on the processing

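Keeping outlier-marked spots and using only genes on all 4 arrays were chosen after seeing the data. Every other setting kept the count of changed genes within 1.5 times of 910, except each slide alone. Slide 1 alone gave 530 changed genes (262 higher, 268 lower) and slide 2 alone 487 (250 higher, 237 lower), with fewer arrays and fewer genes tested. Keeping marked spots gave 1449 (686 higher, 763 lower) and 507 at least 2-fold, with more genes tested. Genes on all 4 arrays gave 604, of which 289 were lower and 182 at least 2-fold, with fewer genes tested. Leaving out 1 replicate gave 670 to 813 changed genes (333 to 400 higher, 335 to 413 lower) and 227 to 376 at least 2-fold. The slide as a random block gave 1293 at a consensus correlation of -0.731, with opposite dye orientations on each slide. That negative correlation narrows the standard errors, so the setting says little about the stability of the count. No main call changed sign under any setting that tested it. The share of calls that were higher was 49.3%, and 44.1% to 51.3% under the alternatives fixed in advance. The medians of all tested genes stayed within 0.04 of 0.

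Camera called 1 list in every setting, except for 2 with slide 1 alone, which added translation factors. Camera with an estimated correlation called 0 lists, since the estimate for ribosomal proteins was 0.325. By contrast fry, which tests whether a list moves, on balance, 1 way, called 5 of 6. These were ribosomal proteins, translation factors, pyrimidine synthesis, DNA replication, and cell division and wall. All were lower, each at a fry adjusted p of 0.0183. Unlike camera, fry does not compare a list with the other genes. The dye model was run in 8 other settings. No gene passed for dye in 7 of them, and scaling between arrays gave 42, for which the cause was not tested. Leaving out the filters on dim probes, which removed no probe, and the series matrix, which repeats the processed intensities, 457 values of the 29 named genes were computed under alternatives. Of these, 439 stayed on their side of the threshold, 18 in 8 genes fell short of it and none reversed. The values for ileS were computed with marked spots kept. About 99% of spots were well above background.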

Other observations

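The tests on ribosomal protein genes and on neighbouring genes were written down before their results were seen. Values here keep outlier-marked spots unless stated, and the stretches named were chosen after their values were seen. Of the 1449 changed genes, 372 stood in 53 stretches of at least 5 neighbouring genes that all rose or all fell, while 1000 shuffled orders gave a median of 5 such stretches and at most 15, with a longest of 12 genes. The longest, SACOL0136 to SACOL0151, held 16 genes, none with a symbol, that all rose, with a median log2 ratio of 1.16. A stretch of 14 genes that rose, SACOL0989 to SACOL1003, held spxA, which encodes a redox-responsive regulator of transcription. Decreases included 12 genes from SACOL2228 to SACOL2239, 11 of them named ribosomal protein genes such as rplC and rpsC, with a median of -1.23, and 11 genes from SACOL1073 to SACOL1083 around purH, with a median of -1.16. The stretch of groEL and groES and a stretch of 6 genes that held pgk and tpiA rose.

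The next gene after ileS, SACOL1207, rose by 1.17 ± 0.25 (SD, n = 4, limma adjusted p = 0.000131), and the gene after that, lspA, for the lipoprotein signal peptidase, was at -1.06 ± 0.24 (SD, n = 4, limma adjusted p = 0.000201). In the 9 genes from SACOL2042 to SACOL2050, both arrays with mupirocin in Cy5 lay above both with mupirocin in Cy3 in all 9 genes, an order that 25.4% of all 2465 genes showed. None of the 9 passed for dye (limma adjusted p of at least 0.0818).

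Neighbouring genes changed together. Log2 ratios of genes side by side in the NCTC 8325 order correlated at 0.527 across 2018 pairs, while 1000 shuffled orders gave at most 0.073. Position on the array is argued against, since spots side by side on the array correlated at 0.0266. The correlation fell to 0.308 between genes 2 apart and to 0.025 between genes 20 apart. This is consistent with shared transcripts of neighbouring genes, a hypothesis, since no transcript boundaries were measured.

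The decrease of ribosomal protein genes was set against 2 technical explanations. These genes are bright, yet 0% of 10000 random lists matched on brightness had a median as low as -1.02 in the main setting, and the lowest random median was -0.74. The random lists were not matched on the correlation among ribosomal protein genes, estimated at 0.325. Medians of lists so correlated can spread more widely, so the 0% is not a p-value for the list. Under 5 other background corrections, centrings and scalings the median was at most -1.01, so the decrease did not hinge on the choice among them. Each of them again left the median of all tested genes near 0, at -0.0242 to 0.0155. They therefore cannot decide whether setting the arrays to 0 accounts for part of the decrease. A response of the cells to mupirocin may account for the decrease, as a hypothesis. The list and its test were fixed in advance, but no other data were used to examine it. A shift of all transcripts would not be visible on these arrays.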
